A study of Mus musculus with 8 samples.

How the data were processed

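Gene expression was measured on 8 two-colour oligonucleotide microarrays (Agilent whole mouse genome design) in nephron progenitor cells sorted from mouse kidneys at embryonic day 15.5. The cells were sorted for the enhanced green fluorescent protein (EGFP) carried by a Six2-Cre transgene, which is active in the nephron progenitors of the cap mesenchyme. Per the labels, 4 pools came from kidneys with floxed Hdac1 and Hdac2 alleles (mutant) and 4 from kidneys with unfloxed alleles (wildtype), both with the transgene. The labels call the pools biological replicates. Each pool was labelled with Cy5 from 0.5 µg of total RNA. Cy3 held RNA of wildtype pool 1 on every array, so the array of wildtype pool 1 carried the same RNA in both dyes.

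The deposited scanner files hold spot intensity values on a linear scale: the median brightness of each spot and of its local background in each dye, and processed signals that were background-subtracted and dye-normalized by Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. The deposited value table of the series holds log10 ratios of Cy5 over Cy3 for the same arrays. Its columns matched the log ratios of the scanner files on feature number, with correlations of at least 0.999999 and a largest difference of 0.005, so its scale and direction were settled. Column medians of that table were 0 on 7 arrays and 0.00483 on the wildtype 2 array.

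The median spot signals of the scanner files were corrected for background with limma 3.58.1 in R 4.3.3 (normexp, offset 50) and normalized by loess within each array, with control and outlier spots at weight 0 and no scaling between arrays. Mean spot signals, which the design fixed before the data were examined had named, were not analysed here, and median signals took their place. Spots of one probe were averaged. A probe was kept if it was well above background in Cy5 on at least 3 of the 4 arrays of one group, which left 30364 of 55681 probes. Gene symbols came from the accession of each probe, without its version, matched to a RefSeq gene table of assembly GRCm38.p6. This named 27509 probes with 20887 symbols, and other probes keep the accession or probe name. That table was used only for names and for which genes neighbour each other, since the array annotation refers to another build. One probe per gene, the one with the highest mean Cy5 level, gave 22694 genes tested, 14989 of them with a symbol. Of the 22694 genes, 334 lacked a value in at least 1 sample and stayed out of the list tests. Array signals give no count of molecules, and the number of arrays limits the precision.

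Arrays were compared before averaging. Between log2 levels of 10 and 12 (5807 probes), Cy3 levels, which come from the same RNA, differed between arrays with a median absolute deviation of 0.0663 to 0.114 over 21 pairs of arrays without wildtype 2. Cy5 levels of wildtype pools 3 and 4 differed by 0.0838 and those of mutant pools 3 and 4 by 0.0893. The other 19 Cy5 pairs differed by 0.163 to 0.499. Pools 3 and 4 of each group therefore differed by no more than the technical noise, and their mean was counted as 1 sample. All comparisons are between 3 wildtype and 3 mutant samples, where the design fixed beforehand had 4 and 4. Whether the pools of a group share animals is not given in the sources used here.

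Pool numbers are shared by the groups. Deviations from the group mean of the same-numbered samples correlated across 22694 genes with r = 0.496 for pool 1, 0.543 for pool 2 and 0.527 for pools 3 and 4, and differently numbered samples with r from -0.0777 to -0.455. The negative values are partly forced, since deviations from a group mean cancel within the group. From the same-numbered correlations, and not from a label, the numbers were taken to pair the samples. Values of a fit with the pool number as a replicate block are printed beside results whose call or count they change. In Cy3, which holds one RNA, the same-numbered correlations were 0.0855, 0.103 and 0.194. All arrays lie on 1 slide from 1 scan. Mutant arrays fill one row of the slide and wildtype arrays the other, and the column is the pool number, so row and group cannot be told apart.

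Groups were compared with limma (lmFit and eBayes, two-sided) on log2 ratios of Cy5 over Cy3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. An exact permutation test of 3 against 3 samples cannot give a p below 0.1. Values are given as the log2 difference, mutant minus wildtype, with the standard error (SE) of the limma fit (of the blocked fit where a gene passed only with the block), or as group means with the standard deviation (SD). The groups' own means are relative to the Cy3 reference. Gene lists were tested with camera (preset correlation between genes of 0.01), with an estimated correlation and with fry beside it. The 30 lists (853 entries, 852 with a current symbol) were written before the data were examined. They cover kidney cell types, signalling pathways, HDAC complexes, cell cycle, stress and other gene classes, and 29 of them had at least 5 measured genes.

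The text names Hdac1, Hdac2 and Six2; the 12 largest rises and 12 largest falls among genes with an adjusted p under the threshold, a change of at least 2-fold, no overlap between the 4 mutant and 4 wildtype arrays, a signal well above background on all 4 arrays of the brighter group and a gene symbol that is no placeholder; and from each list up to 4 members with an adjusted p under the threshold or, where there were none, the 2 members with the highest Cy5 level. That rule was fixed beforehand. Named as well, after their values were seen, are genes from the same rule applied to the blocked fit with a change in the same direction in all 3 pairs, called genes without a symbol, and list members that passed when adjusted over the list alone. Some genes that these rules name are not reported here; they are included in all counts, medians and tests.

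The steps were tested on simulated data with the levels and spreads of the 22694 genes and 200 changed genes, besides a shifted list of 25 genes whose calls count as true. Without the block, 6% of genes changed by 0.5 on the log2 scale were recovered, 76% of those changed by 1, 98% by 1.5 and 100% by 2, with 7 false calls among 147. With the block, 46% of changes of 0.5 and 100% of the larger ones were recovered, with 12 false calls among 191. That list, shifted by 0.5, was called by camera with and without the block, and an unshifted one was not. Noise was drawn independently for each gene, so this does not test camera's calls of lists whose genes vary together.

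Alternatives covered the background correction, dye normalization and scaling, the Cy5 channel alone, the deposited value table, the filter on dim probes, the choice of probe, the variance model, the replicate block and leaving out each array. Chosen after seeing the data were the 8 arrays as separate samples, whole samples or pairs left out, and the mutant 1 and wildtype 2 arrays both left out.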

Results

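Nephron progenitors marked by the transcription factor Six2 were sorted from embryonic day 15.5 mouse kidneys, and wildtype cells were compared with cells that, per the labels, carried a conditional deletion of the histone deacetylases Hdac1 and Hdac2. The 8 arrays held 4 wildtype and 4 mutant pools, counted as 3 samples per group because pools 3 and 4 of each group differed by no more than technical noise. Between 28150 and 33982 of 55681 probes were well above background in Cy5 on 7 arrays, and 48627 were on the wildtype 2 array. In the Cy3 reference channel the same array had 47833 such probes and the others 29617 to 34468. On the mutant 1 array the median SD between different probes of one gene was 0.245 on the log2 scale (3916 genes), against 0.0826 to 0.142 on the others. The lowest value was that of the wildtype 1 array, which carried the same RNA in both dyes.

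The deleted genes were examined first. The histone deacetylase Hdac1 was measured by 3 probes, and each was lower in the mutant sample of all 3 pairs. The brightest probe read 0.16 ± 0.03 in wildtype and -0.14 ± 0.06 in mutant samples (SD, n = 3), a log2 difference of -0.30 ± 0.09 (SE). The other probes differed by -0.40 ± 0.09 and -0.57 ± 0.14 (SE), so that mutant levels were 81.4%, 75.7% and 67.4% of wildtype by the 3 probes. None of the probes passed the threshold in limma (adjusted p = 0.477 for the brightest), and the exact permutation test gave 0.1 for each, the smallest p that 3 against 3 samples allow. Hdac2, measured by 1 probe, differed by -0.13 ± 0.14 (SE, adjusted p = 0.84) and was lower in 2 of 3 pairs. Where these probes lie relative to the floxed exons was not analysed here, and a probe outside the deleted part does not check the deletion. Six2, the transcription factor that maintains the progenitors, differed by -0.13 ± 0.14 (SE, adjusted p = 0.839) at its brighter probe and by -0.17 ± 0.14 at the other.

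**Figure D1:**
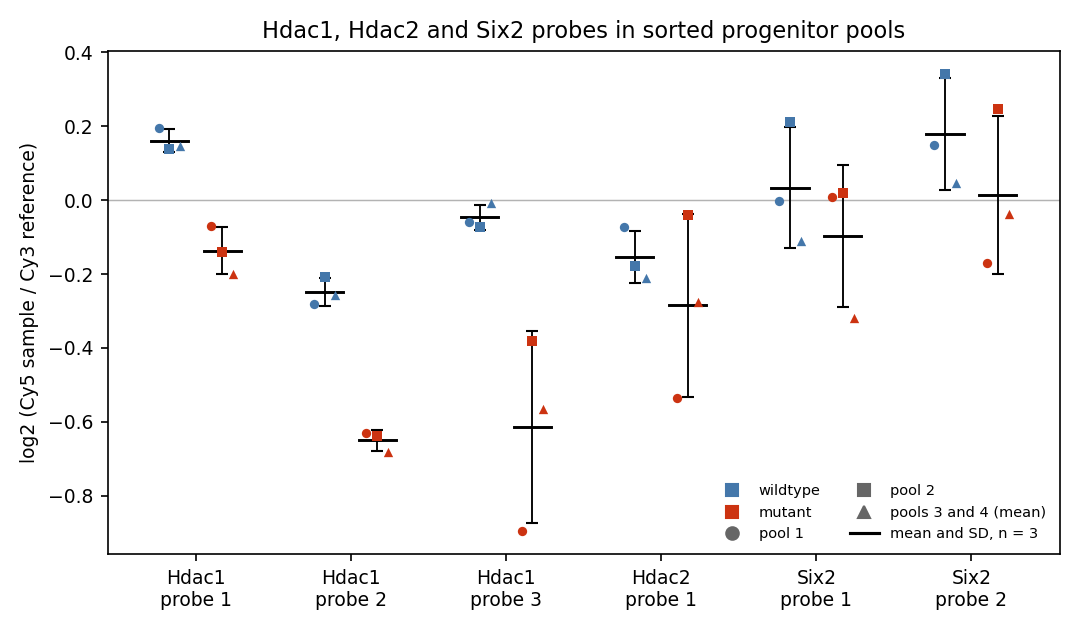
Log2 ratio of Cy5 sample over Cy3 reference for each probe of Hdac1, Hdac2 and Six2, probes numbered from the brightest, with 1 point per sample and bars for mean and SD (n = 3). The mutant samples lie below the wildtype samples at all 3 Hdac1 probes, and the groups overlap at Hdac2 and Six2.

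Few genes passed the test, and their changes were large. Cited1, a transcriptional co-regulator that marks the least committed nephron progenitors, fell most, from -0.09 ± 0.19 in wildtype to -2.81 ± 0.13 in mutant samples (SD, n = 3), a 6.6-fold fall (adjusted p = 0.00283). Traf1, a TNF receptor-associated adaptor, fell 3.61-fold (log2 -1.85 ± 0.10 SE, adjusted p = 0.00288), and Kazald1, a secreted Kazal-domain protein, fell 3.12-fold (log2 -1.64 ± 0.15, adjusted p = 0.0311). Sln, which encodes the calcium pump inhibitor sarcolipin, rose 6.1-fold (log2 2.61 ± 0.18, adjusted p = 0.00788). Ptpn5, a tyrosine phosphatase best known from brain, rose 3.35-fold (log2 1.74 ± 0.14, adjusted p = 0.0198), and Chrna6, a nicotinic acetylcholine receptor subunit, rose 2.21-fold (log2 1.14 ± 0.10, adjusted p = 0.0311). Each of the 6 moved in the same direction in all 3 pairs. Of 32 alternatives, Cited1 lost its call in 3, Traf1 and Sln in 5, Ptpn5 in 10, Kazald1 in 12 and Chrna6 in 13. The Chrna6 difference ranged from 0.99 to 2.15 over them. With a trended, robust variance model all 5 genes called were higher, so Cited1, Traf1 and Kazald1 did not pass.

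In limma, 8 of 22694 genes passed at an adjusted p under 0.05, 4 higher and 4 lower in the mutants, all by at least 2-fold; 1641 genes had an unadjusted p under 0.05. The 2 called genes without a symbol were the transcript ENSMUST00000022460 (log2 -1.74 ± 0.10 SE) and the probe A_55_P2174736 (log2 1.39 ± 0.13). The transcript was well above background on 3 of 4 mutant arrays, and its difference reached -3.13 over the alternatives. The 6 genes named above are those that met the naming rule. With the replicate block, 34 genes passed, 8 higher and 26 lower, 32 of them by at least 2-fold, and these included all 8. The count fell to 4 without wildtype replicate 1, to 4 without wildtype replicate 2, to 1 without the sample of wildtype pools 3 and 4 and to 3 without that of mutant pools 3 and 4. Counting the 8 arrays as separate samples gave 257 genes.

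**Figure D2:**
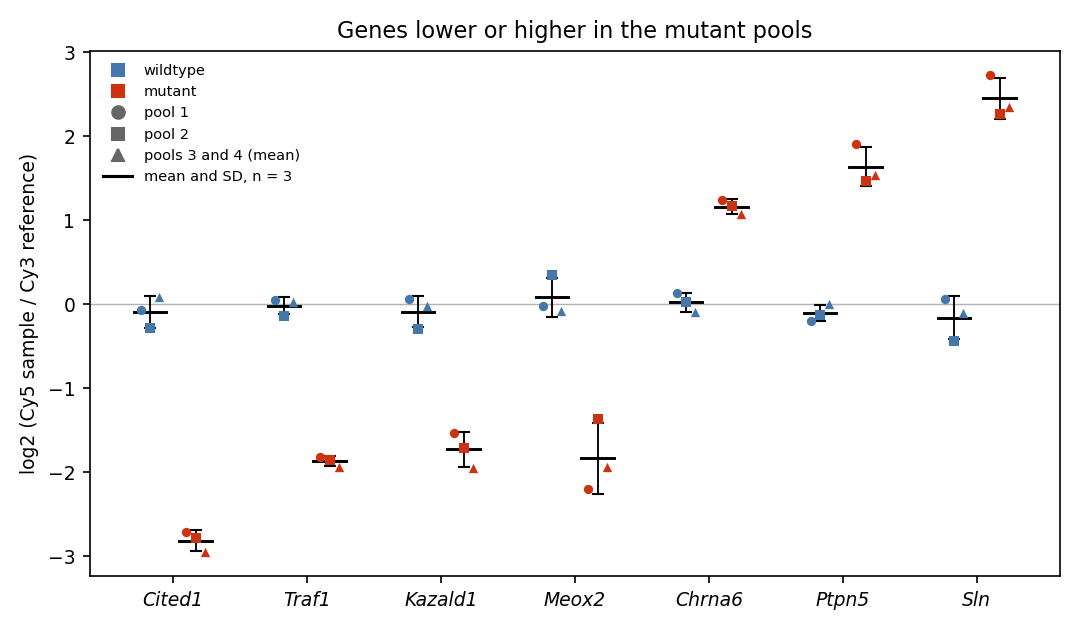
Log2 ratio of Cy5 sample over Cy3 reference for 7 genes, with 1 point per sample and bars for mean and SD (n = 3). Cited1, Traf1, Kazald1 and Meox2 lie lower and Chrna6, Ptpn5 and Sln higher in every mutant sample. In the reported 3 against 3 fit over all genes, Meox2 passed with the replicate block and not without it.

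The replicate block, which compares pools of the same number, added 26 genes, many of them with a wide spread between pools. The homeobox gene Meox2 fell by 1.92 on the log2 scale (SE 0.12, adjusted p = 0.0317 with the block, 0.0814 without). The somitic transcriptional repressor gene Ripply2 fell by 1.55 (SE 0.11) and R3hdml by 2.40 (SE 0.14), and Elmod1 rose by 1.09 (SE 0.08), each with an adjusted p from 0.0317 to 0.0328. Of the other lower genes, 2 are on the proximal tubule list and 2 on the loop of Henle and distal tubule list. Hsd3b4 fell by 1.70 (SE 0.13), the potassium channel gene Kcnj1 by 1.59 (SE 0.12), Hdc, which makes histamine, by 1.52 (SE 0.10), and the claudin gene Cldn2 by 1.49 (SE 0.12); the calcium-binding protein gene S100g fell 2.82-fold. Kcnj1 and Cldn2 were well above background on 3 of 4 mutant arrays. Without the block, leaving out single arrays or samples moved Hsd3b4 between -2.68 and -0.90 and Hdc between -2.39 and -0.74. S100g then lay between -2.32 and -0.79, Kcnj1 between -2.21 and -1.07 and Cldn2 between -1.98 and -1.05. Leaving out the pool 1 pair or the pair of pools 3 and 4 left 0 genes called in the blocked fit, and leaving out the pool 2 pair left 46. Without the pool 1 pair and without the pair of pools 3 and 4, 3176 and 1493 genes had an unadjusted p under 0.05, against 2869 with all pairs. Fewer samples also lower the power of these fits, so the loss of calls does not show that they came from those pairs.

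Genes of the nephron progenitor list were lower in the mutants as a group. Of 32 measured members 2 fell (Cited1 and Traf1), 0 rose and 30 did not pass; adjusted over the list alone, 8 fell. The further 6 were Meox2, the homeobox gene Uncx (log2 -0.82 ± 0.12 SE), Tmem100 (-1.09 ± 0.16), Capn6 (-1.20 ± 0.20), Spock2 (-0.65 ± 0.15) and the integrin ligand gene Npnt (-0.66 ± 0.17). With the block, 3 members fell over all genes, and 14 fell and 2 (Fgf20 among them) rose when adjusted over the list alone. The list's median log2 difference was -0.23 and camera called it (adjusted p = 1.26e-07). Adjusted p = 0.635 with an estimated correlation, and fry gave 0.094. In either direction, its members changed by fry (adjusted p = 7.1e-05).

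The renal vesicle and pretubular aggregate list, the first epithelial stages that form from these progenitors, had a median of -0.37 (camera adjusted p = 1.58e-05; adjusted p = 0.635 with an estimated correlation). None of its 29 measured members passed, over all genes or adjusted over the list alone. With the block 0 passed over all genes, and 15 fell and 1 (Bmp2) rose when adjusted over the list alone, among them Lhx1, a homeobox gene needed for renal vesicle patterning (log2 -1.12 ± 0.20 SE), the Notch ligand gene Dll1 (-0.76 ± 0.09) and Irx1 (-1.26 ± 0.17). Its brightest members Wt1 and Ccnd1 differed by -0.37 ± 0.13 and -0.41 ± 0.12 without the block (adjusted p = 0.559 and 0.465). The Notch pathway list was not called by camera (25 measured, median -0.02). Adjusted over the list alone, Hey1 fell (log2 -0.66 ± 0.10); with the block Hes5 (-1.14 ± 0.11), Dll1, Lfng (-0.69 ± 0.11) and Jag1 (-0.40 ± 0.09) fell too. The brightest members, Rfng and Notch3, differed by 0.25 ± 0.13 and 0.29 ± 0.15. Among 18 measured Wnt/beta-catenin targets (median 0.15) 0 passed over all genes and 1 rose when adjusted over the list alone, the transcription factor gene Sp5 (0.91 ± 0.12); Wnt4 differed by 0.24 ± 0.11. Among 19 FGF/ERK feedback genes (median -0.05) 0 passed over all genes and 1 fell when adjusted over the list alone, Egr1 (-0.61 ± 0.11); Fgfr1 and Etv5 differed by -0.15 ± 0.17 and 0.26 ± 0.17. With the block, Fgf20 rose and Il17rd fell as well over the list alone.

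Lists of differentiated nephron segments were lower in the mutants. The proximal tubule list had a median of -0.93 over 27 measured genes (camera adjusted p = 2.45e-06; adjusted p = 0.635 with an estimated correlation), with medians of -0.98, -0.50 and -1.04 in the pairs of pools 1, 2 and 3 and 4. None of its members passed without the block. With the block 2 fell over all genes (among them the scaffold protein gene Pdzk1, -1.46 ± 0.10 SE), and 17 fell and 0 rose when adjusted over the list alone. These include Hnf4a, a transcription factor of proximal tubule identity (2.84-fold lower), and the endocytic receptor genes Lrp2 (-0.95 ± 0.16) and Cubn (-1.25 ± 0.24). Without the block, leaving out single arrays or samples moved Hnf4a between -1.94 and -0.81, Lrp2 between -1.69 and -0.29 and Cubn between -1.93 and -0.63. The list's median was -0.49 without mutant replicate 2 and -0.38 without the sample of wildtype pools 3 and 4, and the list was called in both. Pool 2 differed from the other pools on this list by a median of -1.11 in wildtype and -0.91 in mutant samples. The loop of Henle and distal tubule list had a median of -0.41 over 22 genes (camera adjusted p = 0.002; adjusted p = 0.635 with an estimated correlation). Adjusted over the list alone, 3 of its members fell, Bsnd (-1.28 ± 0.19), Emx1 and Umod, the uromodulin gene (-0.91 ± 0.24), and 1 rose, Ppp1r1b (0.74 ± 0.16); none passed over all genes. With the block 2 fell over all genes, Kcnj1 and Sim2 (-1.06 ± 0.09), and 10 fell and 3 rose over the list alone. Its brightest members Wfdc2 and Irx3 differed by 0.25 ± 0.15 and 0.15 ± 0.22. The podocyte list had a median of -0.29 over 21 genes (camera adjusted p = 0.00592; adjusted p = 0.635 with an estimated correlation) and no member passed; with the block 0 passed over all genes and 5 fell over the list alone, among them Ptpro (-1.34 ± 0.14). The loop of Henle and distal tubule median was -0.21 without the sample of wildtype pools 3 and 4 (adjusted p = 0.037). Without mutant replicate 2 the loop of Henle and distal tubule list (adjusted p = 0.14) and the podocyte list (0.109) were not called. The podocyte list was also not called without the sample of wildtype pools 3 and 4 (0.108), and its median was -0.13 without mutant replicate 1. Cdkn1c and Actn4, its brightest members, differed by 0.11 ± 0.19 and 0.15 ± 0.19.

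**Figure D3:**
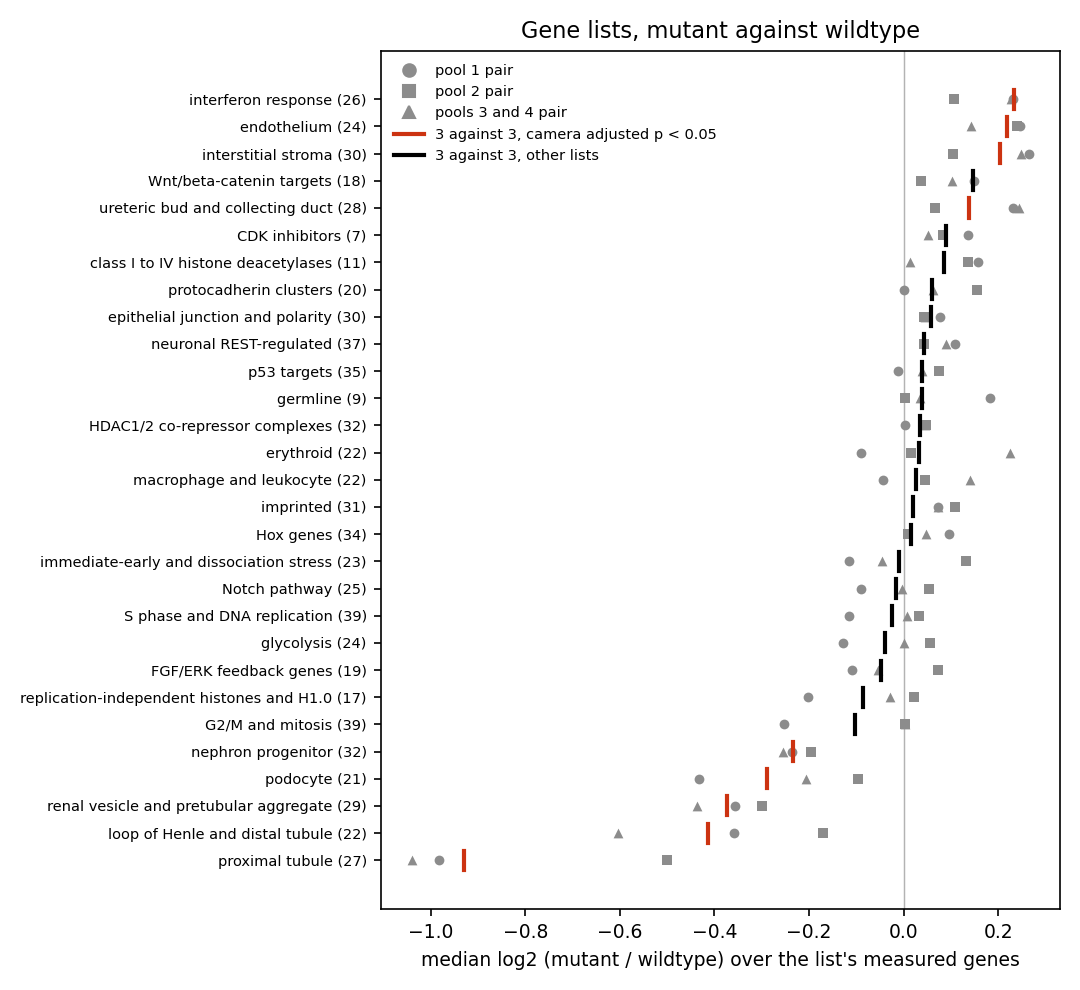
Median log2 difference, mutant minus wildtype, over the measured genes of each of 29 gene lists (number of genes in brackets), for each pair of pools (grey) and for 3 against 3 samples (bars, red where camera's adjusted p is under 0.05). The proximal tubule list lies lowest at -0.93, and stroma, endothelium and interferon lists lie highest, at 0.20 to 0.23.

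Markers of other kidney cells that a sort could carry over were not lower with them. The interstitial stroma list had a median of 0.20 over 30 measured genes (26 with a higher mutant mean; camera adjusted p = 0.000339) and the endothelium list 0.22 over 24 (20 with a higher mean; adjusted p = 0.00158), each with adjusted p = 0.635 with an estimated correlation. The ureteric bud and collecting duct list had a median of 0.14 over 28 (adjusted p = 0.0244, and 0.635 with an estimated correlation). Its median became -0.02 when arrays were centred on spike-ins, a setting that moved the median of all genes to -0.15. That setting also took the stroma, endothelium and interferon response medians to 0.05, 0.06 and 0.08, and camera still called these lists. Without the wildtype 2 array the ureteric bud and collecting duct median was -0.0033 (adjusted p = 0.154) and the endothelium median 0.09 (0.0633), neither called, while stroma stayed called (0.17, 0.000622). Without the sample of mutant pools 3 and 4 the ureteric bud and collecting duct (0.474) and endothelium (0.0602) lists were not called either, and the stroma median was 0.12 (adjusted p = 0.0403). Without mutant replicate 2 the stroma median was 0.34 and the ureteric bud and collecting duct median 0.25. None of the members of these 3 lists passed without the block. With the block 0 passed over all genes, and on the ureteric bud and collecting duct list 8 rose over the list alone, among them the GDNF receptor gene Ret (0.66 ± 0.12 SE), Wnt9b (0.41 ± 0.09) and Sox9 (0.41 ± 0.09), and 1 fell, Foxi1 (-0.83 ± 0.10). The brightest stroma genes Col1a2 and Aldh1a2 differed by 0.24 ± 0.17 and 0.34 ± 0.16, the endothelial genes Egfl7 and Cd34 by 0.30 ± 0.14 and 0.27 ± 0.14, and the epithelial gene Krt18 by 0.30 ± 0.17. The interferon response list had a median of 0.23 over 26 genes (camera adjusted p = 0.00132; adjusted p = 0.635 with an estimated correlation), and 0.11 without the sample of mutant pools 3 and 4 (adjusted p = 0.0437). Without the wildtype 2 array the interferon median was 0.15 (camera adjusted p = 0.000927). No member passed without the block, and with it 0 passed over all genes and 8 rose over the list alone, among them Oasl2 (0.40 ± 0.10) and Rsad2 (0.50 ± 0.10). Ifitm3 and Ifitm1 differed by 0.21 ± 0.17 and 0.18 ± 0.19. Macrophage and leukocyte genes (22 measured, median 0.03, mean -0.01) and erythroid genes (22 measured, median 0.03) were not called. Adjusted over the list alone Cd74 fell (-0.61 ± 0.09); Csf1r, Pf4, Hba-a2 and Hba-a1 differed by 0.01 ± 0.25, 0.22 ± 0.17, 0.26 ± 0.23 and 0.03 ± 0.27.

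Camera called 9 of 29 lists without the block and 10 with it; the further list was G2/M and mitosis (median -0.10 over 39 genes; adjusted p = 0.0489 with the block, 0.0712 without, and 0.677 with the block and an estimated correlation). Its pair medians were -0.25 for pool 1 and 0.0039 and 0.0032 for the others; its median was 0.0096 without mutant replicate 1 (adjusted p = 0.925) and -0.0002 in the blocked fit without the pool 1 pair (0.632). Neither fit called a list with an estimated correlation, and fry called 0 in one direction, with or without the block. In either direction fry called 5 lists, which besides the nephron progenitor list were the neuronal REST-regulated (adjusted p = 0.000196), Hox genes (0.0252), Notch pathway (0.0259) and germline (0.0259) lists. With the block that test called 17 lists, the germline list not among them (0.108). Other splits of the 6 samples called up to 13 lists by camera.

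Neuronal genes regulated by REST, a repressor that recruits HDAC1 and HDAC2, were not called as a group (37 measured, median 0.04, camera adjusted p = 0.0712) but were in 6 of 34 alternatives, among them without the wildtype 2 array (median 0.09, adjusted p = 0.00307), and none passed over all genes. Adjusted over the list alone, 6 rose and 2 fell. Mapk8ip2 rose (log2 0.95 ± 0.18 SE), as did Celf4 (0.85 ± 0.14), Stmn2 (0.77 ± 0.10), Nsg2 (0.58 ± 0.10), Kif5c (0.43 ± 0.11) and Bex2 (0.37 ± 0.10), while Nefl (-0.83 ± 0.16) and the prohormone convertase gene Pcsk2 fell (-1.11 ± 0.22); Pcsk2 fell over all genes with the block, and over the list alone 6 rose and 3 fell, Dcx being added. Cplx2 differed by 0.22 ± 0.12. Of 34 measured Hox genes (median 0.02), 0 passed over all genes and 3 rose when adjusted over the list alone, Hoxc4 (0.86 ± 0.16), Hoxd12 (0.68 ± 0.17) and Hoxc6 (0.49 ± 0.09), and 1 fell, Hoxb2 (-0.36 ± 0.09), which did not pass with the block; Hoxb7 and Hoxb6 differed by -0.13 ± 0.10 and -0.38 ± 0.15.

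The other lists were not called without the block. Among 11 histone deacetylases (median 0.09) the brightest besides Hdac1 was Hdac7 (0.09 ± 0.10 SE), and among 32 members of the HDAC1 and HDAC2 co-repressor complexes (median 0.04) Rbbp4 and Chd4 differed by -0.11 ± 0.10 and 0.07 ± 0.16. Medians were 0.04 over 35 p53 targets, 0.09 over 7 CDK inhibitors, -0.02 over 39 S phase and DNA replication genes, -0.09 over 17 replication-independent histones, -0.04 over 24 glycolysis genes, -0.01 over 23 immediate-early and dissociation stress genes, 0.02 over 31 imprinted genes, 0.04 over 9 germline genes, 0.06 over 20 protocadherin genes and 0.06 over 30 epithelial junction and polarity genes, whose mean was -0.02. No member of these lists passed without the block over all genes, and only Egr1, also an immediate-early gene, passed over a list alone. With the block Cldn2 fell over all genes, and over the list alone Perp and H2bu2 fell and Plk2 rose. Among the brightest cell cycle genes, Mcm6 differed by -0.14 ± 0.09, Mcm7 by -0.05 ± 0.10, Birc5 by -0.02 ± 0.09, Cdc20 by 0.03 ± 0.09 and the CDK inhibitor gene Cdkn2d by 0.36 ± 0.12. Differences were -0.04 ± 0.09 for Rps27l, 0.19 ± 0.12 for Abhd4, -0.02 ± 0.11 for H2aj, -0.31 ± 0.17 for H2az1, -0.19 ± 0.13 for Gapdh, -0.18 ± 0.18 for Ldha, -0.12 ± 0.09 for Hsp90aa1, 0.09 ± 0.09 for Dnajb1, 0.02 ± 0.20 for H19, 0.21 ± 0.14 for Taf7l, 0.02 ± 0.15 for Rhox5, -0.01 ± 0.09 for Pcdhga9, 0.17 ± 0.10 for Pcdhb21 and -0.27 ± 0.19 for Lama1. The 4 measured sex-linked genes were too few for a list test; Xist differed by -0.26 ± 0.11 and Ddx3y by 0.46 ± 0.28, and Eif2s3y was higher by 0.64 ± 0.17 when adjusted over the list alone (adjusted p = 0.0285, and 0.0512 with the block).

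As a technical control, the Cy3 channel was compared between the arrays that carry mutant pools and those that carry wildtype pools. It holds the same wildtype RNA throughout. None of 22694 genes passed in limma, and 877 had an unadjusted p under 0.05 (1768 without the wildtype 2 array). The latter count, over 7 arrays, exceeds the 1641 genes of the 3 against 3 comparison. Small row effects are therefore not excluded. Genes within 10 Mb of Hdac1 or Hdac2, where DNA of the donor strain of a floxed allele could lie, were compared with other genes: 0 of 344 were called, against 6 of 14646 (Fisher's exact test, two-sided, p = 1), too few calls to show an excess. With the 8 arrays as separate samples these counts were 5 of 344 and 206 of 14646 (Fisher's exact p = 0.817).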

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

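Of the tests in this part, that of a property shared by pool 1 was written down before its result was seen; the others were chosen after. Array measures were compared within the 4 arrays of each group (Cy5) or over all 8 arrays (Cy3), in 12 groups, 5 of which held an array apart from the rest; chance gives about 1 in 20. These groups count arrays, and arrays 3 and 4 of a group hold 1 sample. The rate of 1 in 20 takes the arrays as independent, so it does not hold for the Cy5 groups.

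The mutant 1 array stood apart from the other mutant arrays. It had 28150 Cy5 probes well above background, against 30264 to 30678, and a median SD between probes of one gene of 0.245, against 0.119 to 0.137. A fault of hybridisation or scanning of the whole array, in both dyes, is argued against by Cy3. It spread by at most 0.0976 between this array and another, within the 0.114 seen among the other arrays. The wildtype 2 array was left out on both sides. A fault in Cy5 alone would not show in Cy3 and stays open. Deviations of 2 probes of a gene on this array correlated with r = 0.171 across 3916 genes. This lay below the 0.274 to 0.388 of the other mutant arrays, although the deviations were larger. Probe-specific differences in the labelled RNA, such as its quality or labelling, would give this. Deviations were taken from the other samples of the group, so those of the other mutant arrays contain the mutant 1 array and are no independent range. On the wildtype 1 array r was 0.182, with smaller deviations. The difference between 2 probes of a gene correlated with that on the wildtype 1 array (r = 0.617), so a property shared by pool 1 of both genotypes may be involved, in the RNA or in the column of the slide, which is the same for both. A difference in the cells of that pool stays open for the part that probes share.

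The wildtype 2 array was raised on dim probes. It had a spike-in slope of 0.775, against 0.845 to 0.848 on the other wildtype arrays, 47833 Cy3 probes well above background, against 29617 to 34468, and a median Cy3 signal of 181, against 58 to 75.5. The median Cy5 signal of the ERCC control probes, which the comparisons do not use, was 165 on this array and 64 to 74.5 on the others. More transcripts in the cells of this pool would raise Cy5 alone, and the 47833 probes in Cy3, from the RNA of another pool, argue against it. The ERCC probes were raised in Cy3 as well, to 79 against 33 to 46, as non-specific binding on this array would give. The negative control probes did not show this in both dyes. Their median signal was 68.5 in Cy5, against 61 to 63 on the others, but 38 in Cy3, within the 31 to 39 of the others. Non-specific binding therefore stays a possibility that 1 of these control classes does not bear out in Cy3. No biological explanation remains to be tested for the Cy3 part.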

How the results depend on the processing

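Alternatives with 8 arrays as separate samples, with whole samples or pairs left out, or with mutant 1 and wildtype 2 both left out were chosen after seeing the data. Against 8 genes changed, all at least 2-fold, the count was 5 with loess and spike-in centring (1 higher, 4 lower), 1 in the Cy5 channel alone (lower), 5 with eBayes trend and robust (all higher), 825 with array weights (41 at least 2-fold), 34 with the replicate block (32), 257 with 8 arrays as separate samples (37) and 744 with both 8 arrays and the block (99). Under the block it was 0 without the pool 1 pair, 46 without the pool 2 pair (46 at least 2-fold) and 0 without the pair of pools 3 and 4. Leaving out single arrays or whole samples gave 1 to 10 genes for both counts; leaving out both doubted arrays gave 7, of which 6 were shared. Scaling settings moved the share of higher calls from 50% to 20% with spike-ins and 0% in Cy5 alone, and the median of all genes to -0.15 and 0.13. The cause was not tested. Other settings gave 7 to 12 genes.

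Gene lists called were 8 to 11 (9 reported; leaving out samples, 8 to 10), and 0 with camera and an estimated correlation and 0 with fry. Single lists lost or gained a call in places: the 9 called lists kept theirs in 271 of 306 alternatives and reversed in 0. Some alternatives could not differ, so these counts overstate the agreement. Scaling by quantiles of the average intensity left the log ratios unchanged, and the trended variance model does not enter the list tests. The deposited value table repeats the processed signals. Of 34 alternatives each, the ureteric bud and collecting duct list lost its call in 10, podocyte and endothelium in 5, loop of Henle and distal tubule in 4, interferon in 3 and the others in 2, while G2/M gained one in 10, neuronal in 6, imprinted in 5 and protocadherin in 1. S phase and DNA replication, not called, was called upward (median 0.0631) with the mutant 1 and wildtype 2 arrays left out. Hdac1 at its brightest probe ranged from -0.45 to -0.19 and passed only with array weights (-0.35, adjusted p = 0.022); another probe passed with 8 arrays as separate samples (-0.41, adjusted p = 0.0265). Hdac2 ranged from -0.29 to 0.22 and never passed. Without single samples they ranged from -0.33 to -0.27 and from -0.25 to -0.0043. The Cy3 control called 0 genes in its 19 alternatives, which include no dye normalization and no whole samples or pairs left out, and the floxed neighbours gave p of at least 0.627 in their 34. The 8 called genes kept their direction in all 255 alternatives and their call in 186, counts that include the scaling that left the log ratios unchanged. The block changed no gene or camera call other than those given here and beside the results. Dim probes limit the rest: the filter left 22694 genes, and 37067 without it gave 10 calls.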

Other observations

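Of the tests in this part, the one on the row of the slide was written down before its result was seen; the others were chosen after. Besides the genes named by rule, the blocked fit called 3 more higher genes with a symbol or accession, the Polycomb-related gene Sfmbt2 (log2 0.95 ± 0.08 SE), the retinoic acid synthesis gene Aldh1a3 (0.92 ± 0.08) and XM_003688767 (1.02 ± 0.08). It also called as lower Dao (-1.46 ± 0.09), Gc (-1.43 ± 0.10), Pcp4 (-1.38 ± 0.09), Ugt2b38 (-1.33 ± 0.09), Vil1 (-1.29 ± 0.11), Cltrn (-1.27 ± 0.09), Acsm2 (-1.20 ± 0.09) and Serpinf2 (-1.13 ± 0.08). Gc, Ugt2b38 and Acsm2 were well above background on 3 of 4 mutant arrays, and Ugt2b38 ranged from -2.67 to -0.63 over the alternatives. Without the block these 11 had adjusted p from 0.0792 to 0.798.

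For the lower tubule genes in mutant pools, fewer cells of other kidney types carried through the sort would lower markers of each type. The 9 pair medians of the stroma, endothelium and ureteric bud lists were all above 0, the lowest at 0.0675. The macrophage and leukocyte list and the erythroid list lay below 0 in the pool 1 pair, at -0.04 and -0.09. Both were above 0 in the other pairs. Without the wildtype 2 array the stroma, endothelium and ureteric bud lists had medians of 0.17, 0.09 and -0.0033, against -1.31 for the proximal tubule list. With spike-in centring their medians were 0.05, 0.06 and -0.02, against -1.085. Both groups hold every pool number, so differences between pool numbers that both genotypes share cancel with or without pairing. They could not give the fall, and the pairs do not test them. The 3 pair medians of the proximal tubule list averaged -0.84 (95% interval by t from the spread between the 3 pairs, -1.57 to -0.10). This list has the lowest median of the 29, and the interval makes no allowance for that choice. Camera with the block and an estimated correlation gave it an adjusted p of 0.311. A row of the slide that reads these spots lower in both dyes alike would cancel in the ratio, so Cy3 cannot decide on it. In Cy3 the 49 proximal and distal tubule genes were higher in the mutant row by a median of 0.11, against -0.77 in the ratio. A higher Cy3 level in that row by itself lowers the ratio, but this difference is smaller than the fall. A biological difference between the genotypes, such as fewer cells that have begun to form tubule, stays open and untested, as do a lower carry-over of tubule cells alone and a row effect on Cy5 alone, which the design confounds with genotype; counts of tubule cells among the sorted cells, not analysed here, would bear on the first 2.

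Splits of the samples were counted for each kind of call. With 3 against 3 samples there are 10 splits, too few for a share under 0.05. The real split called 8 genes, all at least 2-fold, and the highest of the others 1, so 1 split in 10 called as many. For the lists the real split called 9 and the highest of the others 13, and 4 splits called as many; the splits that called more lists parted only 1 of the 3 pairs. Among the 4 splits that part all 3 pairs, with the block, the real one called 34 genes and the others 0, and 10 lists against at most 6; in each case 1 split called as many. For the Cy3 control, which called 0 genes, all 35 splits called 0, with 877 genes at an unadjusted p under 0.05 in the real split and 83 to 1099 in the others.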
